A study of Mus musculus with 4 samples.

How the data were processed

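Total RNA of 2 EpiSC samples and 2 parnate/mAMFGi samples, which the labels call biological replicates, was labelled with biotin and hybridised to Illumina mouse bead arrays. Per the labels' protocols, cRNA was made with the Illumina TotalPrep kit. The values used were the authors' processed intensities, on a linear scale, with 1 value per probe and array. Their software, background step and normalization are not given in the sources used here. The deposited intensities had nearly equal quartiles on the 4 arrays (medians 50, 50.3, 52 and 52), which points to a normalization between arrays. No value was at or below 0 and the lowest was 25.5, so a background level or an offset remained in every value and compresses the folds of dim probes. A second deposited table of signals before normalization has 8 columns of values per probe, 4 of signals and 4 of detection, under names that match no label. These 8 columns were not used, so no probe could be called detected or not, and the background correction and detection filter planned before the data were examined were replaced by the processed intensities of all 25697 probes.

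Values were log2-transformed with no pseudocount, no further normalization and no filter. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), and p-values were adjusted by Benjamini-Hochberg over all 25697 probes with a threshold of 0.05. Each probe had 2 residual degrees of freedom, moderated with 11.8 prior degrees of freedom around a prior SD of 0.10 on the log2 scale. The comparison has 2 groups of 2, so p-values rest on this shared estimate of the spread. A log2 fold change is parnate/mAMFGi minus EpiSC. The 2 arrays of a group held identical values for 163 (EpiSC) and 159 (parnate/mAMFGi) probes, against 127 to 148 between groups, and were treated as separate samples. The sources used here name no slide or scan date, so such batches were not tested.

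Gene names came from the platform annotation supplied with the probes. Of 25697 probes, 23978 had 1 symbol, 0 had several and 1719 had none. Symbols were compared by gene identifier with a RefSeq gene table of assembly GRCm38.p6, in which 23962 probes were found and 0 symbols needed updating. The table was also used for chromosomes and gene order. A gene is represented by its probe with the highest mean log2 intensity, and 4777 of 16593 genes had more than 1 probe. Of the 98 named genes, 35 had more than 1 probe, and for 8 of these the probes disagreed in call, with none in opposite directions. In each, the probe that did not pass was dim. These probes had log2 fold changes of 0.01 for B2m, 0.23 for Cd59b, −0.02 and 0.17 for Cdk1, 0.05 for Dppa5a, −0.05 for Map2, −0.27 for Pfkl, −0.04 for Pfkp and 0.03 for Snai1.

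Named genes were set before the data were examined. They are the 8 largest rises and 8 largest falls among called genes with a proper symbol, whose arrays do not overlap between groups; 12 genes fixed by name, of which T was not analysed here; and up to 3 members of each list with the largest absolute change. The 27 gene lists covered shared pluripotency, ES cell and inner cell mass, epiblast and EpiSC, primitive streak, endoderm, neural ectoderm, trophoblast, germline, 2-cell stage and fibroblast feeder genes; targets of LIF and STAT3, FGF and ERK, Wnt, activin and nodal, and BMP; LSD1 complex and H3K4 demethylase, DNA methylation, epithelial, mesenchymal, X inactivation center, Y-linked and imprinted genes; and glycolysis, cytochrome c oxidase, MHC class I and interferon, proliferation, and CDK inhibitor and p53 target genes. Each list with at least 3 measured members was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists tested. Camera sets a list against all other genes, whereas fry asks whether its members move one way on balance.

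The fit was tested on simulated data with the probes' own means and with spreads drawn at random from the fitted prior. Of simulated changes of 0.5 on the log2 scale, 40 of 67 were recovered (59.7%), and all 67 of size 1 and 66 of size 2 were. There were 7 false calls, 3.89% of calls. The simulation changed 200 of 25697 probes, whereas 38.4% were called in the data, so its rates need not hold for the data. Of 3 shifted simulated lists, camera called 3 at the preset correlation, 0 at the estimated correlation and fry 1. An estimated correlation thus had little power there. The simulated genes were independent, so the test cannot show how often the preset value calls falsely when members are correlated. Among lists called at the preset value, estimated correlations in the data ran from −0.0901 (endoderm) to 0.345 (cytochrome c oxidase). Alternatives were quantile normalization, normexp background correction with offsets of 50 and 16 (each followed by quantile normalization), scaling to a common median, and cyclic loess. Others were probes above the median mean intensity alone, eBayes with trend or robust, the replicate number as a block, the mean of a gene's probes, and leaving out each array. The eBayes settings do not enter the list tests, so lists keep their main values under them by construction. Figures were drawn with matplotlib 3.10.9.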

Results

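Gene expression was measured on Illumina bead arrays in 2 kinds of mouse cells, with 2 arrays for each kind. Epiblast stem cells (EpiSCs), which are pluripotent cells derived from the postimplantation epiblast, made up the first group. Cells converted from EpiSCs with small molecules and named parnate/mAMFGi in the labels made up the second. Parnate (tranylcypromine) inhibits the histone H3K4 demethylase LSD1. The question was how the genome-wide expression of the converted cells differed from that of the EpiSCs. Per the labels, EpiSCs were grown in serum replacement medium with bFGF and the converted cells in serum medium with LIF, both on irradiated mouse embryonic fibroblasts. Medium and group therefore cannot be told apart. The arrays held 25697 probes, and their median intensities were 50 and 50.3 in EpiSCs and 52 in both parnate/mAMFGi arrays. Over all probes, log2 intensities correlated at r = 0.996 between the EpiSC replicates and at r = 0.998 between the parnate/mAMFGi replicates, against 0.942 to 0.945 between groups. These are correlations across probes, which are not independent replicates.

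The largest rises in parnate/mAMFGi cells were in Dppa5a, Dnmt3l and Rhox5, and the largest falls in Chst1 and Gdpd3. Dppa5a, an RNA-binding protein of pluripotent cells, rose from an intensity of 85.5 ± 1.77 in EpiSCs to 32527 ± 1116 (mean ± SD, n = 2 arrays per group), a log2 fold change of 8.57 (SE 0.09). Dnmt3l, a cofactor of the de novo DNA methyltransferases, rose from 62.3 ± 4.88 to 17800 ± 715, and the X-linked homeobox gene Rhox5 from 118.2 ± 1.27 to 19232 ± 313. Dppa4 (log2 fold change 6.68), the oocyte gene Ooep (6.44), Rbmxl2 (6.23), Xlr4a (6.04) and Tex19.1 (5.75) completed the 8 largest rises as measured. Ooep, Rbmxl2 and Tex19.1 read 46.7, 47.0 and 57.9 in EpiSCs, close to the array medians, so their folds are understated and the order of the largest changes is not fixed. The sulfotransferase gene Chst1 fell from 7139 ± 124 to 89.3 ± 7.78 (log2 fold change −6.32, SE 0.10), and Gdpd3 from 3830 ± 133 to 55.4 ± 2.26. Acot1 (−4.97), Tuft1 (−4.58), the complement inhibitor genes Cd59b (−4.53) and Cd59a (−4.34), the MHC class II gene H2-Ab1 (−4.13) and Adssl1 (−4.13) followed. Adjusted p-values of these 16 genes lay between 1.46e-16 (Dppa5a) and 9.95e-13 (Cd59a) with limma and Benjamini-Hochberg adjustment. Cd59a and Cd59b, and members of the Xlr, Acot and Dppa5 families, have close paralogs whose transcripts a probe may not separate.

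In all, 9870 of 25697 probes (38.4%) passed an adjusted p of 0.05 in limma, 5069 higher and 4801 lower in parnate/mAMFGi cells. Of these, 2512 changed by at least 2-fold, 1177 up and 1335 down. At least 8-fold changes numbered 85 up and 49 down, and at least 16-fold changes 37 up and 9 down. Counted once per gene by its brightest probe, 6878 of 16593 genes changed, 3360 up and 3518 down. Both arrays of one group lay beyond both of the other for 16490 probes, an arrangement that chance alone gives for 33.3% of probes. The lowest intensity was 25.5, so background or an offset remained in the values. Folds are therefore understated where a gene reads low in one group, most of all near the array medians of 50 to 52. This covers Dnmt3l, Zfp42 and Gdpd3, among others.

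**Figure D1:**
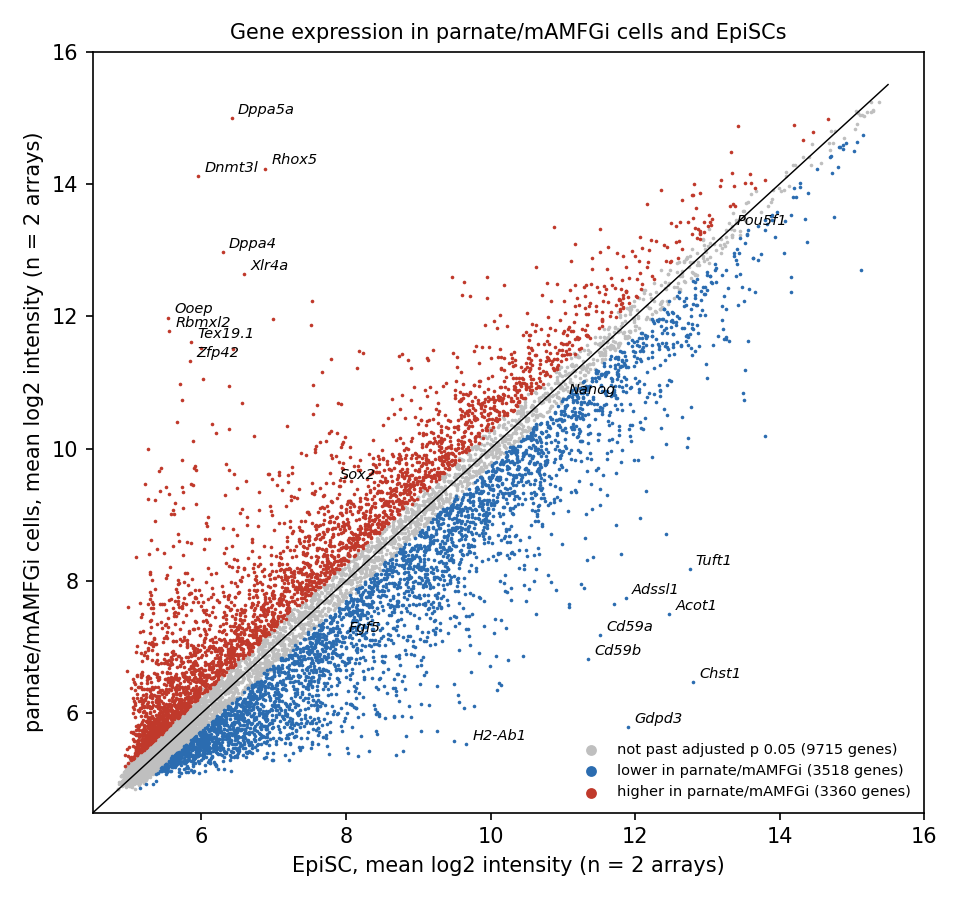
Mean log2 intensity of each gene in EpiSCs (x axis) and in parnate/mAMFGi cells (y axis), with 1 point per gene, n = 2 arrays per group, and a line of equality. The 3360 genes called higher lie above the line and the 3518 called lower lie below it, with Dppa5a, Dnmt3l and Rhox5 farthest above and Chst1 and Gdpd3 farthest below.

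Genes of ES cells and the inner cell mass rose together, while the core factor gene Pou5f1 did not pass the test. Of 18 measured ES cell and inner cell mass genes, 14 rose, 1 fell and 3 did not pass (15 rose when adjusted over the list alone). Besides Dppa5a, the zinc finger gene Zfp42 (Rex1) rose from 57.9 ± 12.5 to 2570 ± 57.3 (log2 fold change 5.49, SE 0.13) and the nuclear receptor gene Esrrb from 86.8 ± 1.63 to 2907 ± 230 (5.06, SE 0.10). Klf4 rose by 2.81, Dppa3 (Stella) by 3.92 and the surface marker Pecam1 by 2.70 on the log2 scale. Gbx2 was the member that fell, by 1.84. With camera at a preset correlation, the list ranked above other genes (adjusted p = 5.57e-12), but the adjusted p was 0.543 with an estimated correlation. Of 11 shared pluripotency genes, 8 rose and 3 did not pass. Adjusted over the list alone, 8 rose and 1, Nanog, fell. The list's camera adjusted p was 8.2e-05, against an adjusted p of 0.543 with an estimated correlation. Pou5f1 (Oct4) measured 10271 ± 909 in EpiSCs and 10199 ± 766 in parnate/mAMFGi cells (adjusted p = 0.964, limma). Nanog measured 2044 ± 5.87 and 1730 ± 60.5 (log2 fold change −0.24, adjusted p = 0.0545, limma); its adjusted p was 0.0209 when arrays were scaled to a common median and ranged from there to 0.33 over 13 alternatives. Sox2 rose by 1.66, Gdf3 by 4.97 and L1td1 by 2.79 on the log2 scale.

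**Figure D2:**
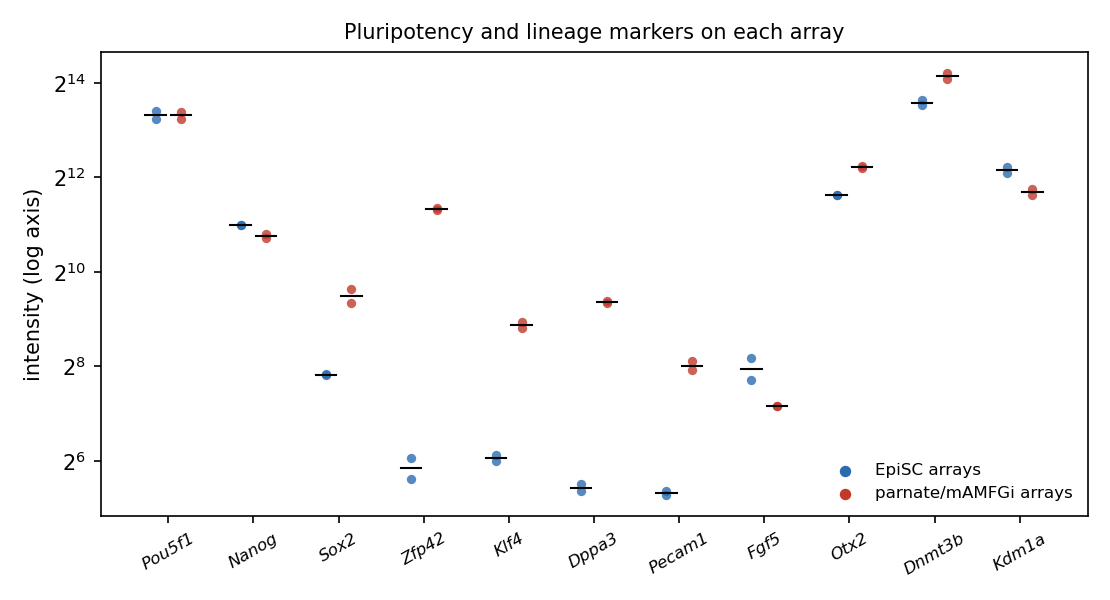
Intensity (log axis) on each array of the genes fixed in advance and measured, in EpiSCs and parnate/mAMFGi cells, with 1 point per array and a bar at the geometric mean of the 2 arrays. Pou5f1 overlaps between groups, whereas the arrays of Zfp42, Klf4, Dppa3 and Pecam1 lie apart, and Fgf5 and Kdm1a are lower in parnate/mAMFGi cells.

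Genes of the postimplantation epiblast went both ways. Of 14 epiblast and EpiSC genes, 4 rose, 5 fell and 5 did not pass (5 rose and 6 fell when adjusted over the list alone). Fgf5, the usual marker of the postimplantation epiblast, fell from 249.9 ± 56.0 to 143.8 ± 0.354 (log2 fold change −0.78, SE 0.13, limma adjusted p = 1.42e-04). The epiblast transcription factor genes Otx2 (0.59) and Pou3f1 (1.19), Fgf15 (1.25) and Dnmt3b (0.57) rose instead. At least 2-fold changes in this list numbered 2 up and 0 down. Among the falls, Sox3 (61.85 to 44.05) and Wnt8a (67.45 to 44.4) read near the array medians. Dnmt3a, Cdh2 and Sox4, which did not pass, were dim in both groups. The list's median was −0.14, its mean 0.02, camera pointed down (adjusted p = 0.767) and fry up (adjusted p = 0.0861). Of 11 primitive streak genes, 1 rose, 4 fell and 6 did not pass (camera adjusted p = 0.0738, with a range of 0.0393 to 0.152 over the 14 alternatives that kept the preset correlation, 3 of them past the threshold). Fgf8 fell from 345.9 ± 16.9 to 51.8 ± 1.13, and Lhx1 and Gsc fell with log2 fold changes of −1.16 and −1.08. The primitive streak gene T was not analysed here. Of 10 neural ectoderm genes, 4 fell and 6 did not pass (camera adjusted p = 0.222), with log2 fold changes of −2.55 for Map2, −1.42 for Nes and −0.38 for Zic1. The Zic1 call was lost without EpiSC replicate 1 (adjusted p = 0.113) and without parnate/mAMFGi replicate 2 (0.176), in a range of 0.00172 to 0.176.

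Among other lineages, 7 of 12 extraembryonic and definitive endoderm genes rose and 5 did not pass, with Amn at 1.40, Sox7 at 1.25 and Hnf4a at 0.74 on the log2 scale. They read 216.4 ± 5.37, 92.4 ± 1.13 and 83.5 ± 1.98 in parnate/mAMFGi cells. Sox17 and Ttr, also among the 7, read 52.4 and 45.5 there, near the array medians. The camera adjusted p of 0.0297 became an adjusted p of 0.559 with an estimated correlation, 0.0522 after normexp correction with offset 50 and 0.0995 on the brighter probes alone. Over the 14 alternatives that kept the preset correlation it ranged from 0.0251 to 0.0995. Of 10 trophoblast genes, 4 rose and 6 did not pass (camera adjusted p = 0.108). Tfap2c, also a germ cell factor, rose from 247.1 ± 4.17 to 1074 ± 7.99, Gata3 by 1.27 and Cdx2 by 0.46 on the log2 scale. Cdx2 read 40.25 in EpiSCs and 55.4 in parnate/mAMFGi cells, near the array medians. None of 7 measured 2-cell stage genes passed in limma (camera adjusted p = 0.586). Their log2 fold changes were at most 0.24 (Tcstv3 and Zfp352) with intensities near the floor, and Tdpoz1 stood at 0.19. Each of these 3 passed under 1 or 2 alternatives, with adjusted p-values down to 0.0212 (Tdpoz1 without EpiSC replicate 2).

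Germline genes rose in part. Of 13 measured, 6 rose and 7 did not pass, with Dnmt3l and Rhox5 at the top and the RNA-binding gene Dazl rising from 53.3 ± 2.05 to 687.1 ± 58.1. The camera adjusted p was 1.41e-04, and the adjusted p 0.559 with an estimated correlation. This list's median log2 fold change was 0.22 and its mean 1.90, so the mean rests largely on the top genes. Meiotic Sycp3 (log2 fold change −0.08), Sycp1 (0.22) and the germ cell helicase Ddx4 (0.22) did not pass. Of 9 genes of the DNA methylation machinery, 3 rose, 1 fell and 5 did not pass (camera adjusted p = 0.137), with Mbd3 rising by 1.81 on the log2 scale beside Dnmt3l and Dnmt3b. The maintenance gene Dnmt1 stood at 0.16 and did not pass. Kdm1a, which encodes LSD1, fell from 4562 ± 302 to 3313 ± 210 (log2 fold change −0.46, SE 0.10, limma adjusted p = 0.00144). Of 10 LSD1 complex and H3K4 demethylase genes, 5 rose, 3 fell and 2 did not pass (camera adjusted p = 0.729), with Hdac1 at 0.94, Rcor2 at 0.70 and Hmg20b at −0.87.

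Signalling target lists were mixed. Of 9 BMP targets, 4 rose, 2 fell and 3 did not pass (camera adjusted p = 0.104). Id1, an inhibitor of basic helix-loop-helix factors, rose from 221.4 ± 7.57 to 2616 ± 237, and Id3 and Id2 rose by 2.11 and 2.10 on the log2 scale. Msx1 rose by 1.66, and the 2 members that fell were the ligand genes Bmp4 (−1.04) and Bmp7 (−0.95). Of 10 LIF and STAT3 targets, 5 rose, 4 fell and 1 did not pass (camera adjusted p = 0.644). The feedback inhibitor Socs3 rose from 650.5 ± 12.3 to 1964 ± 63.1 along with Klf4, whereas Ier3 fell by 2.26. Of 12 FGF and ERK targets, 2 rose, 5 fell and 5 did not pass (camera adjusted p = 0.242). The ERK phosphatase gene Dusp6 fell from 7012 ± 554 to 1591 ± 149, Egr1 by 1.84 and Fos by 1.38 on the log2 scale, while Etv5 rose by 1.25. Of 10 Wnt and beta-catenin targets, 3 rose, 1 fell and 6 did not pass (camera adjusted p = 0.371), with Notum at 2.17, Ccnd1 at 1.20 and Lef1 at 0.78. Of 8 activin and nodal targets, 3 rose, 2 fell and 3 did not pass. Lefty1, a secreted nodal inhibitor, fell from 1077 ± 64.4 to 117.0 ± 0.919, while Nodal rose by 1.03 and Foxh1 by 0.73 on the log2 scale. That list's median was 0.04 and its mean −0.14, camera pointed up (adjusted p = 0.751) and fry down (adjusted p = 0.037).

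The simple epithelial keratin genes Krt8, Krt18 and Krt19 fell. Of 10 epithelial adhesion genes, 2 rose, 7 fell and 1 did not pass. Krt18 fell from 1221 ± 172 to 112.3 ± 8.84 (log2 fold change −3.44, SE 0.11), Krt19 and Krt8 had log2 fold changes of −2.64 and −2.61, and the E-cadherin gene Cdh1 rose by 1.19. The camera adjusted p of 0.0433 became an adjusted p of 0.559 with an estimated correlation. Without EpiSC replicate 1 it was 0.0656, and over the 14 alternatives that kept the preset correlation it ranged from 0.0305 to 0.152, with 8 past the threshold. Passes under eBayes with trend or robust count among these, but those settings do not enter camera. Of 8 mesenchymal genes, 3 rose, 3 fell and 2 did not pass (4 fell when adjusted over the list alone, camera adjusted p = 0.644), with Tgfbi at −1.16, Zeb1 at −0.94 and Snai1 at 0.46. Of 15 fibroblast feeder markers, 8 rose, 4 fell and 3 did not pass (camera adjusted p = 0.222). The collagen crosslinking enzyme gene Lox rose from 59.4 ± 8.13 to 1113 ± 51.6 and Col1a1 from 99.6 ± 14 to 458.0 ± 23.7, while the matricellular gene Ccn1 fell from 1417 ± 127 to 291.8 ± 16.6. Of 10 MHC class I and interferon genes, 1 rose, 4 fell and 5 did not pass (camera adjusted p = 0.232). Psmb9 fell by 1.28, B2m by 1.03 and Tap1 by 0.42 on the log2 scale, the last not past the threshold without parnate/mAMFGi replicate 2 (adjusted p = 0.0714, in a range of 0.00138 to 0.0714).

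Among Y-linked genes, only Eif2s3y read far above the array medians in both groups. It read 1288 ± 29.1 in EpiSCs and 1000 ± 99.5 in parnate/mAMFGi cells (log2 fold change −0.37). Kdm5d fell by 1.19 on the log2 scale, from 127.25 to 55.55, near the floor. Uty, near the floor in both groups, rose by 0.30 (1 rose and 2 fell of 3, camera adjusted p = 0.367). The Uty call was kept in 6 of 13 alternatives (adjusted p 0.0203 to 0.342) and was lost without EpiSC replicate 1 (0.0543), EpiSC replicate 2 (0.0737) or parnate/mAMFGi replicate 2 (0.342) and under 4 scalings (0.0538 to 0.0877). The Eif2s3y call was lost without parnate/mAMFGi replicate 1 (0.155) and after normexp correction with offset 16 (0.0661), in a range of 0.00346 to 0.155. Both measured X inactivation center genes, too few for a set test, rose at low intensity. Xist read 41.5 ± 3.11 and 52.3 ± 5.37, and Rlim rose by 0.67 on the log2 scale. The Xist call was lost without EpiSC replicate 1 (adjusted p = 0.111), without parnate/mAMFGi replicate 2 (0.267) and after normexp correction with offset 50 (0.0942), in a range of 0.0068 to 0.267. Of 15 imprinted genes, 4 rose, 7 fell and 4 did not pass (5 rose when adjusted over the list alone; camera adjusted p = 0.137). The growth factor gene Igf2 fell from 11645 ± 1231 to 1704 ± 195, Grb10 from 4569 ± 813 to 657.5 ± 21.2 and Nnat from 470.5 ± 31.5 to 68.8 ± 5.59, while Impact rose by 1.17 on the log2 scale.

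Nuclear-encoded cytochrome c oxidase subunits rose and glycolysis genes mostly fell. Of 11 subunits, 8 rose and 3 did not pass (1, Cox6b1, fell when adjusted over the list alone). Cox6a1 rose from 10247 ± 735 to 22909 ± 642, Cox5b by 1.11 and Cox4i1 by 0.82 on the log2 scale. The camera adjusted p was 0.00364, and the adjusted p 0.559 with an estimated correlation. Of 14 glycolysis genes, 2 rose, 9 fell and 3 did not pass. The glucose transporter gene Slc2a3 fell from 11820 ± 1496 to 2337 ± 18.4 and Pfkl by 1.57 on the log2 scale, while Pfkp, also a phosphofructokinase gene, rose by 1.61. The camera adjusted p of 0.0297 became an adjusted p of 0.559 with an estimated correlation and 0.0656 without EpiSC replicate 1. It ranged from 0.0141 to 0.152 over the 14 alternatives that kept the preset correlation, 8 of them past the threshold. Passes under eBayes with trend or robust again count among these without entering camera. Of 10 proliferation genes, 4 rose, 4 fell and 2 did not pass (camera adjusted p = 0.595), with Ccne1 at 1.24, Mcm3 at 0.88 and Cdk1 at −0.84. Of 9 CDK inhibitors and p53 targets, 3 rose, 4 fell and 2 did not pass, with Cdkn2a at 2.20, Sesn2 at 1.53 and the imprinted Cdkn1c at −2.01. That list's median was 0.02 and its mean −0.02, and camera pointed down (adjusted p = 0.767).

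**Figure D3:**
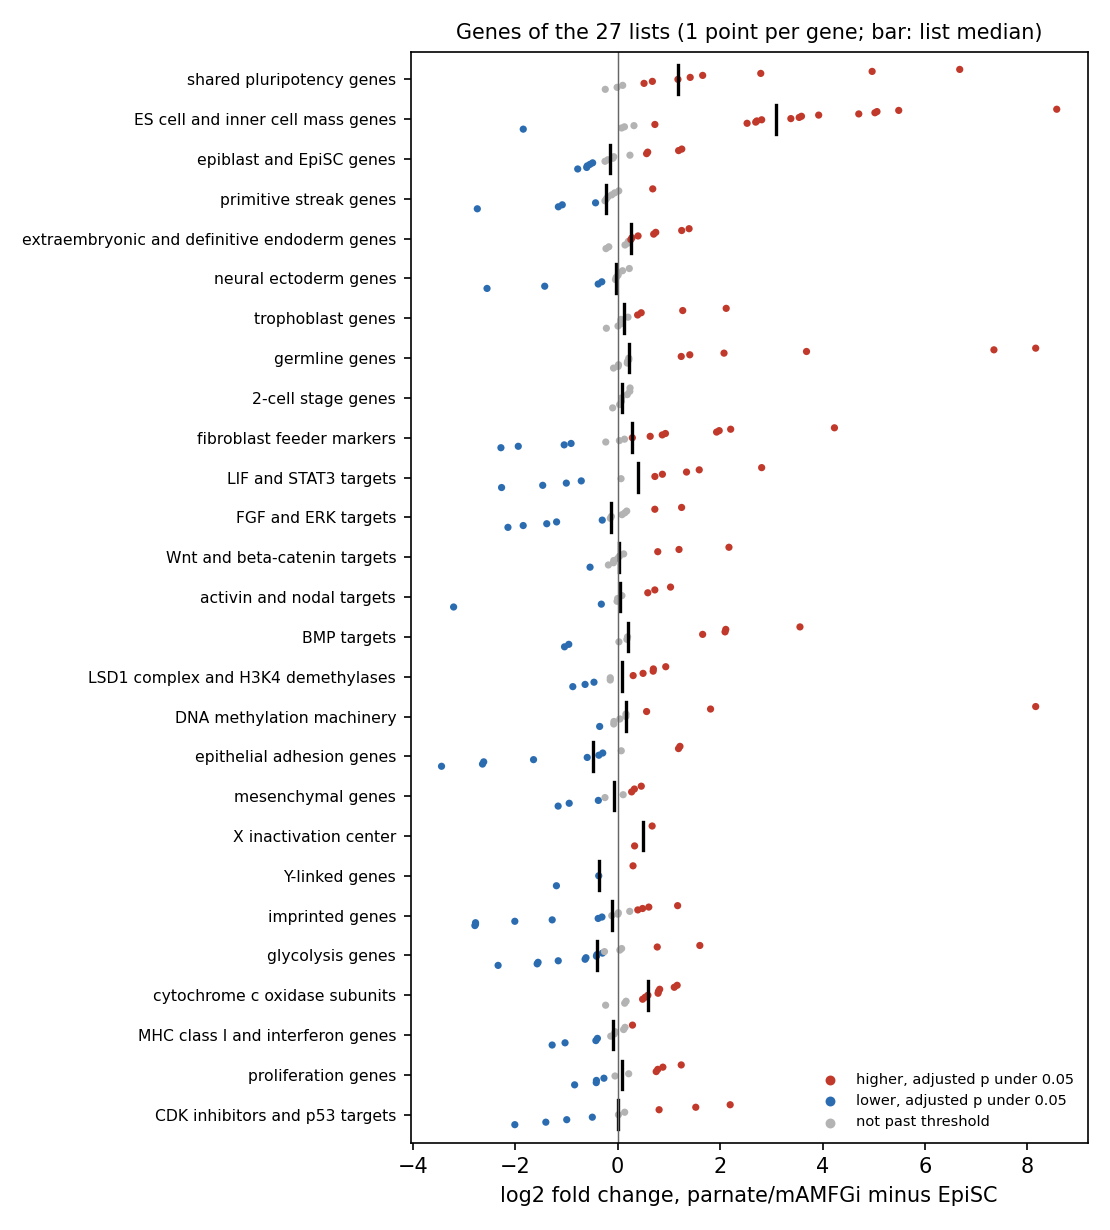
Log2 fold change (parnate/mAMFGi minus EpiSC, x axis) of every measured gene of the 27 lists, with 1 point per gene coloured by its call and a bar at each list's median. ES cell and inner cell mass genes have the highest median, 3.10, and epithelial adhesion genes the lowest, −0.48.

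Calls for genes and lists came from limma, camera and fry on 2 arrays per group, and the number of arrays limits the precision. Fry, which does not compare with other genes, also called 14 lists that camera did not. Its upward adjusted p-values were 0.00326 (DNA methylation), 0.00674 (BMP), 0.00766 (Wnt), 0.00834 (trophoblast), 0.0236 (LIF) and 0.0438 (2-cell stage and feeder). Downward they were 0.0154 (MHC class I), 0.0187 (imprinted), 0.0236 (primitive streak), 0.0306 (neural), 0.037 (activin), 0.04 (Y-linked) and 0.0405 (FGF). The 2-cell list's median log2 fold change was 0.08, near the floor and with no member called. Over all probes the median was itself 0.03, and fry does not set a list against it. The DNA methylation list's median was 0.16 and its mean 1.16, with Dnmt3l at 8.16. Where no other number is given for a list, as many members changed when adjusted over the list alone as over all probes.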

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

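Both counts of changed probes varied under the 13 alternatives run. Probes changed ranged from 7490 to 9986 around 9870, and those changed by at least 2-fold from 1979 (normexp, offset 50) to 2961 (normexp, offset 16) around 2512. Leaving out 1 array gave 7490 to 9625 probes, and 2466 to 2601 with at least 2-fold changes, with the lone array of a group assumed to vary like the others. No probe called in both settings turned its direction, and the share called higher went from 51.4% to between 45.1% (median scaling) and 51.7% (eBayes with trend). For probes and named genes, direction could not change under eBayes with trend or robust, the replicate block or the brighter probes alone. Those settings leave each probe's fold change as it was. The labels number the replicates 1 and 2 in both groups. Deviations of same-numbered arrays correlated at −0.057 over 2 pairs, so the numbers are not taken as a pairing. With the replicate block 9912 probes changed, 2512 of them by at least 2-fold, and no call of a named gene or list was lost or gained. Of the named genes' values under alternatives, 1244 kept direction and side of the threshold, 15 fell below it, 5 rose past it, and 6 were sign changes of Pou5f1, which was not called. For the lists these numbers were 368, 21, 17 and 9, the 9 all in lists that were not called. The 368 include 26 values under eBayes with trend and 26 under robust eBayes, which could not differ because these settings do not enter the list tests. Of the losses 7 came from an estimated correlation, and 14 of the gains from fry, which asks another question. Endoderm, epithelial and glycolysis lists lost their call under some scalings or filters, and the cause was not tested, though the filter on dim probes leaves fewer genes to compare with. The 2 alternatives planned for a table with detection values, no filter and the authors' processed values, are the values used here and so were not run separately. Signal over background limits genes of low intensity, such as Xist, Uty, Zic1 and the 2-cell genes.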

Other observations

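Of the tests below, those of gene families, of the run on chromosome 3 and of the share of X-linked genes among large rises were chosen after the data were seen; those of feeder markers, of the X-linked median and of autosomes were written before their results, though Lox and Col1a1 had been seen by then.

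Groups of genes sharing a symbol root, called families here, were compared with all other genes, 503 families of 5 to 80 genes. With camera at a preset correlation 10 passed, and with an estimated correlation 0 did (adjusted p = 0.995 for each). The Magea family, X-linked genes normally expressed in germ cells, rose in 6 of 6 members (adjusted p = 8.38e-04), from Magea2 (38.3 ± 1.98 to 1022 ± 65.5, n = 2 arrays per group) to Magea1 (log2 fold change 0.41). Over 9 scalings and left-out arrays 5 or 6 members passed. Rhox genes rose in 4 of 8 members (adjusted p = 0.0299), among them Rhox9 (2.55), Rhox6 (1.04) and Rhox10 (1.04) besides Rhox5. Of 25 genes named Tex, for testis expressed, 9 rose and none fell (adjusted p = 0.0299), with Tex14 at 3.87 and Tex19.2 at 3.36. A shared root does not make all members paralogs. Where they are close paralogs they share sequence, so single members are uncertain.

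Other families mostly fell. All 6 Tceal genes (adjusted p = 0.00612; Tceal5 at −1.41) and 4 of 5 Armcx genes (adjusted p = 0.0299) did, and Armcx2 went from 3425 ± 79.0 to 794.0 ± 25.7. The 2 families are not separate findings: all 6 Tceal and 5 Armcx genes lie on the X chromosome between Cenpi and Tsc22d3, the second largest run of neighbouring genes (median −0.75, 21 of 31 fell), which did not pass when gene order was shuffled (permutation p = 0.076). Among 35 genes named H2-, most of them MHC genes, 13 fell and none rose (adjusted p = 0.0454), including the class II genes H2-Ab1 and H2-DMa (−2.28). Carbonic anhydrases fell in 8 of 12 members and rose in 1 (adjusted p = 0.0454), led by Car14 (−3.06), which lies in the chromosome 3 run below, and Car11 (−2.81), and syntaxins fell in 10 of 13 and rose in 1 (adjusted p = 0.0299), led by Stx7 (−1.66). Casein kinases (Csnk) fell in 6 of 8 (adjusted p = 0.0301) and genes named Mapk fell in 9 of 16 and rose in 2 (adjusted p = 0.0454). None of the 10 families' medians changed sign under the 9 scalings and left-out arrays. Other families lie together too. All 35 H2- genes are on chromosome 17, 11 of them in the span of its largest run, which did not pass when shuffled. All 6 Magea and all 8 Rhox genes are on the X chromosome. Camera at a preset correlation of 0.01 treats such members as nearly independent. Rhox5, Magea2 and Magea5 are counted again among the X-linked rises below.

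Fibroblast feeder markers were higher in parnate/mAMFGi cells for 8 of 15 genes. More feeder fibroblasts in the parnate/mAMFGi samples may account for part of this, since both cultures held feeders, but both bounds set in advance were missed: 53.3% rose where 66.7% was needed, and 4 fell, enough to argue against it. The bound on falls was wrong, because the 4 (Thy1, Fstl1, Ccn1, Ccn2) had EpiSC intensities of 549.8 or more, a baseline that would hide a small share of fibroblasts. Of 9 markers under an intensity of 200 in EpiSCs, a limit and a reading set afterwards, 7 rose. Postn (35.2 to 38.6) and Tagln (62.4 to 64.0) did not pass. A low baseline leaves little room to fall but does not force a rise. Since the limit was set after the values were seen, these 7 rises decide nothing for or against feeders. More feeders are thus neither shown nor argued against here. They cannot be told apart from a change in the cells' own matrix genes, which was not tested.

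X-linked genes stood among the largest rises, with 7 of 609 (1.15%) rising at least 8-fold against 59 of 15958 other genes (0.37%). They were Rhox5, Xlr4a, Fmr1nb, Magea2, Magea5, Fthl17f and Gm773. More active X chromosome copies in parnate/mAMFGi cells are argued against: the median log2 fold change of X-linked genes above the median intensity lay −0.070 from that of autosomes (95% bootstrap interval −0.17 to 0.05), where 0.3 or more was set as needed. The bootstrap drew genes as if independent, so its interval leaves out the spread between arrays and may be too narrow. Whether the effect is one on a small number of X-linked genes stays open: the odds ratio of 3.13 (95% interval 1.20 to 6.91, Fisher's exact p = 0.0105, adjusted p over 20 chromosomes 0.21) restates the pattern, so that test is void and supports no explanation of it.

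A run of neighbouring genes on chromosome 3 fell together: in the gene order of GRCm38.p6, the 31 genes above the median intensity from Tmod4 to Mtmr11 had a median log2 fold change of −1.13, and 25 fell, 4 rose and 2 did not pass, with Mcl1 going from 11689 to 4816 and Arnt from 547.6 to 204.9. Over scalings and left-out arrays the median stayed between −1.19 and −0.89. Chance order of genes is argued against, since none of 1000 shuffles reached this median (permutation p = 0.001, the smallest they can give; highest 0.93), though shuffling ignores that neighbours can be regulated together. A copy number difference of the segment cannot be told apart from joint regulation of the region: 80.6% of the run fell, but the range it was tested against (74.2% to 96.8%) was set by the run's own median, so that test is void. A gained or lost autosome cannot be told apart from a partial change, because chromosome 3 lay −0.21 from the other autosomes (95% bootstrap interval −0.29 to −0.10), between the bounds set for and against it, and its 395 genes outside the run lay −0.18 from them (−0.25 to −0.06), while the intervals of 4 other autosomes (5, 12, 14 and 19) excluded 0 as well, chromosome 12 at 0.14 and chromosome 14 at −0.14. These intervals were also drawn over genes and leave out the spread between arrays.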
